A study of Mus musculus with 4 samples.

How the data were processed

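RNA from 4 samples of C2C12 cells (2 Ctrl, 2 Bex at 10 µM, all after 48 h) was amplified, labelled with biotin and hybridised to Affymetrix mouse gene arrays, per the labels' protocols. The authors deposited a table of log2 values made by RMA (background correction, quantile normalization and median polish over probes) in Affymetrix Expression Console with core exons, per the labels; no version is given. RMA across arrays evens out overall level, so a shift of most transcripts would not show. A second deposited table, made with Transcriptome Analysis Console per the submitters' processing notes, holds 559 transcript clusters with the authors' log2 averages per group, a signed fold change (a score that is Bex over Ctrl where positive and minus Ctrl over Bex where negative), an ANOVA p-value and an FDR p-value, per the file headers. Every fold change in it is 1.5 or more in size and every ANOVA p-value lies under 0.05, the highest being 0.049968. The build and annotation release behind it are not given in the sources used here. Its log2 averages differ from the group means of the value table by a median of 0.0705 (Bex) and 0.0712 (Ctrl) and by up to 1.13.

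Arrays were assigned to groups and replicate numbers by their titles. No duplicate arrays were found, since any pair shared only 30 to 58 identical values. The main comparison was Bex minus Ctrl over all 35557 clusters with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, without a filter or covariates, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors are those of limma's moderated fit, and intervals are at 95%. The spread between replicates depended on level, with a median SD (log2) of 0.167 among clusters of low values, 0.128 among the middle ones and 0.0758 among those of high values, in equal parts. Control clusters of the array were not removed, because the files do not mark them.

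Clusters were named only through the authors' deposited table, where 545 had 1 symbol and 14 had several; the latter were not used as genes. Of the 545 symbols, 544 were found in a RefSeq gene table of assembly GRCm38.p6, which updated 42 of them; names are printed as the authors gave them. That table also told which genes neighbour each other, and none of its coordinates were used. For 9 genes with several clusters the one with the highest mean was taken, and no gene had clusters of opposite direction. Before the data were examined, 33 gene lists were fixed for camera, a test of list members against all other genes. As rows outside the authors' table have no name here, camera, its variants and fry were not run, and the split into higher and lower was tested by Fisher's exact test against the other named genes, a choice made after the files were seen. Only rows past the authors' cutoffs enter it, so it says nothing of members that differed less.

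Genes were named by a rule fixed in advance. It took the 12 largest increases and decreases past the main threshold (none passed), the 2 members of largest difference in each list where none passed, and a fixed set of 19 genes; it named 51, of which 1 is not reported here. The 12 largest differences per direction among all named clusters were added later, and other list members are named without this rule. Alternatives fixed in advance were the replicate number as a block, a variance trend, a median shift, quantile normalization, leaving out the 30% of clusters with the lowest mean (below 4.57), the mean of a gene's clusters, each array left out, other thresholds and a fold cutoff alone. Added later were combinations with the variance trend, a plain ANOVA, leaving out low cluster IDs, and other ways to count list genes.

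The fits were tested on simulated arrays for Bex against Ctrl (35557 clusters, 200 changed, 10 runs). The main fit recovered 0% of 1.5-fold, 3.2% of 2-fold, 54.0% of 4-fold and 73.0% of 8-fold changes. The variance-trend fit recovered 5.4%, 19.8%, 65.4% and 80.0%, and each fit made 1.3 false calls per run on average. On the real arrays the main fit called 0 clusters, and even Sprr2g, 19.8-fold higher, had a limma adjusted p of 0.0682. The simulated rates may therefore overstate what the main fit can find here. With shuffled directions, 2 of 1200 list tests passed, and a list set to move one way in full passed in 100 of 100 shuffles. Shuffling removes any co-regulation within a list, so these rates do not cover lists whose genes move together. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used for lists and plots.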

Results

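Transcript levels were measured in C2C12 cells, a mouse myoblast line that can fuse into myotubes in culture. Confluent cells spent 48 h in a basal medium for adipogenesis, either alone (Ctrl) or with 10 µM of the compound labelled Bex. From knowledge of the study, and not from the labels, Bex is bexarotene, an agonist of the retinoid X receptors (RXRs), nuclear receptors that pair with PPARs, LXRs and retinoic acid receptors. The study's title speaks of reprogramming towards brown fat, and its design holds 1 comparison, Bex against Ctrl. Each group had 2 arrays, which limits the precision of every value. The value table held 35557 transcript clusters per array, on a log2 scale, with medians of 5.78 and 5.80 on the Ctrl arrays and 5.77 and 5.76 on the Bex arrays. Across clusters, which are not independent replicates, Pearson's r was 0.991 between the Ctrl arrays, 0.9888 between the Bex arrays and 0.9862 to 0.9879 between arrays of different groups. The labels mention 2 batches of cells without tying arrays to them, so p-values describe the spread between these arrays, part of which may be technical.

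Among genes that could be named, PPAR targets and genes of fatty acid and cholesterol synthesis were mostly or all higher with Bex, most genes of the contractile apparatus were also higher, and most matrix genes were lower. Fabp3, a carrier protein for fatty acids, was 11.4-fold higher (log2 difference 3.51 ± 0.20, SE, n = 2 per group). Cd36, a fatty acid transporter, was 8.28-fold higher (3.05 ± 0.18), and Insig1, an endoplasmic reticulum protein that controls sterol synthesis, was 6.93-fold higher (2.79 ± 0.13). Pparg, the nuclear receptor that directs fat cell formation, was 3.62-fold higher (1.85 ± 0.09). Myh1, a fast-fibre myosin heavy chain, was 4.01-fold higher (2.00 ± 0.09), whereas Saa3, an acute-phase protein, was 5.28-fold lower (log2 difference −2.40 ± 0.25). For each of these 6 genes both Bex arrays lay beyond both Ctrl arrays. The same held for 558 of the 559 clusters of the authors' deposited table. Its cutoffs on these same arrays largely force this, so it adds no support.

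Despite these sizes, 0 of the 35557 clusters passed limma's test at an adjusted p of 0.05, and the lowest adjusted p was 0.0682. At an unadjusted p below 0.05 there were 4189 clusters, against 1778 that chance alone would give, and a test of each cluster by its own variance alone, added after the data were seen, called 1. At an adjusted p of 0.1 limma called 80 clusters, 59 higher and 21 lower, of which 69 could be named. With a prior variance that follows the level, an alternative fixed in advance that is called the variance-trend fit from here on, 427 clusters passed at 0.05, 271 higher and 156 lower. These covered 301 named genes, 194 higher and 107 lower. Without the 6669 clusters whose IDs lie below those of the authors' table, many of which may be array controls that the files do not mark, the main test called 297 of 28888, 202 higher and 95 lower, a setting added after the data were seen. The count of the variance-trend fit was 0 without either Ctrl array, 23 without Bex 1 and 32 without Bex 2, where the spread came from the other group alone and the single array was assumed to vary like it. As the main test called 0, gene differences are given as values, as higher or lower, and passing refers to the variance-trend fit unless the main test is named.

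**Figure D1:**
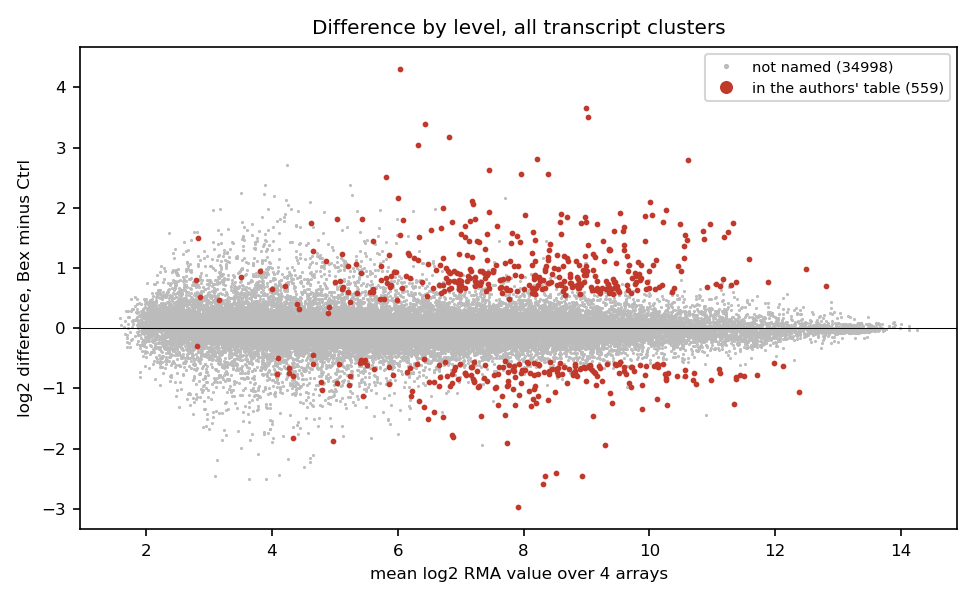
Log2 difference of Bex minus Ctrl (vertical axis) against the mean log2 RMA value over the 4 arrays (horizontal axis), with 1 point per transcript cluster. Red points are the 559 clusters of the authors' deposited table, the others are grey, and the highest point is Sprr2g at 4.31, a gene dim on the Ctrl arrays.

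Gene names came from the authors' deposited table of clusters at 1.5-fold or more, which held 559 clusters, 347 higher and 212 lower, for 536 genes with a single symbol. Of these genes 336 were higher and 200 lower, or 62.7% higher. That table was selected on the same arrays, so the counts below are not independent evidence of a direction. They compare each list, fixed before the data were examined, with the other named genes by a two-sided Fisher's exact test adjusted over 12 lists with at least 5 named genes. The test counts genes as independent, whereas genes of a list can move together in the same dishes, so its p-values may be too low. Of 830 listed genes 140 were named, and the other members were not analysed here. The main test over all clusters passed 0 members of any list, whereas each named member of every list passed when adjusted over the list alone, which follows from the selection of the table. Counts of passing members below depend on the variance-trend fit. With the clusters of lowest mean left out of the main test instead, 9 PPAR targets and 4 genes of fatty acid synthesis passed. So did 8 genes of cholesterol synthesis, 6 contractile genes and 0 matrix genes. The variance-trend fit passed 13, 9, 16, 13 and 7 of them, in the same order.

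Among the PPAR targets, 15 of 34 listed genes were named, 14 higher and 1 lower (adjusted exact p = 0.0308), and 13 passed. Besides Fabp3 and Cd36, the higher genes included Fabp4, the fatty acid carrier of fat cells, at 5.88-fold (2.56 ± 0.16), and the lipid droplet protein gene Plin2. The exception was Txnip, an inhibitor of thioredoxin. Named genes of adipocyte differentiation were 13 higher and 2 lower of 40 listed, a split that did not pass (adjusted exact p = 0.0892), although 13 members passed singly. Dgat2, which makes triglycerides, was 5.90-fold higher (2.56 ± 0.10), and the lipid droplet coat gene Plin1 was 3.23-fold higher (1.69 ± 0.18). Lower were Cav1, the main protein of caveolae, and Cebpd, a transcription factor of early adipogenesis. The PPAR target and adipocyte lists share Cd36, Fabp4, Lpl and Acsl1.

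All 11 named genes of fatty acid synthesis, of 21 listed, were higher (adjusted exact p = 0.0259), and 9 passed. Lpin1, a phosphatidate phosphatase, was 2.74-fold higher (1.46 ± 0.10) and the desaturase Fads2 was 2.72-fold higher (1.44 ± 0.08). Lpin1 and Agpat2 are also in the adipocyte differentiation list. When counting only genes at 1.5-fold or more in each same-numbered pair of arrays, a setting added later, the calls for fatty acid synthesis (adjusted exact p = 0.0643) and PPAR targets (0.0626) were lost. Over the other settings these p-values lay between 0.0111 and 0.0261 and between 0.0144 and 0.0311. The list test uses only directions, which a block or a variance trend cannot change, so these ranges say little of stability. The 6 named LXR targets of 22 listed were all higher without passing as a list (adjusted exact p = 0.107), and 5 passed singly. They were led by Lpl, the lipoprotein lipase, at 2.78-fold (1.47 ± 0.08), and by the fatty acid synthase Fasn at 2.31-fold (1.21 ± 0.09). Lpl is also a listed PPAR target, and Fasn, Srebf1 and Scd1 are also in the fatty acid synthesis list. Fatty acid oxidation had only 3 named genes of 30, too few for the test, and all were higher, among them the acyl-CoA thioesterases Acot1 at 2.31-fold and Acot2 at 2.27-fold. These 3 genes, Acot1, Acot2 and Acsl1, are also listed PPAR targets.

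Brown fat genes were named in 6 of 30 cases, and all 6 were higher, a split that did not pass (adjusted exact p = 0.107), with 4 passing singly. Fgf21, a secreted metabolic hormone, was 2.87-fold higher (1.52 ± 0.09), and Ucp3, a mitochondrial uncoupling protein of muscle and brown fat, was 2.33-fold higher (1.22 ± 0.14) and did not pass. Ppargc1a, a coactivator of mitochondrial genes, was 1.57-fold higher (0.65 ± 0.15; limma adjusted p = 0.293) and did not pass either. The others were Acot2, Cox8b and Elovl6. Fgf21, Ucp3 and Acot2 are also listed PPAR targets, Elovl6 is also listed for fatty acid synthesis, and Fgf21 also for the unfolded protein response. These lists are therefore not separate evidence. Of 19 genes chosen in advance to be reported whatever their values, 5 were named, namely Pparg, Ppargc1a, Fabp4, Plin1 and Pax7. The other 14, among them Ucp1, Prdm16, Cidea, Ebf2 and Myod1, were not analysed here, nor was any gene of the beige fat list.

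Cholesterol synthesis was the list with the lowest p. Of its 25 genes 19 were named, all 19 higher (adjusted exact p = 0.00171), and 16 passed. The median log2 difference was 1.05, with a range from 0.66 for the lowest to 2.79 for Insig1. Idi1, the isomerase of the isoprenoid building block, was 3.75-fold higher (1.91 ± 0.15). Also higher were Hmgcs1, Sqle, Lss and Cyp51, enzymes along the route to cholesterol.

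In the muscle contractile list, 21 of 59 genes were named, 20 higher and 1 lower (adjusted exact p = 0.00350), and 13 passed. The median log2 difference was 0.96. Myh8, the perinatal myosin heavy chain, was 4.18-fold higher (2.06 ± 0.17). Myosin heavy chains are near-identical copies whose probes can share signal, so the separate values of Myh1, Myh3, Myh4 and Myh8 are uncertain. Outside that family 16 of 17 named genes were higher, including Ttn, Neb, Myl1, Tnni1 and Ryr1. The list also holds the creatine kinase Ckm and a pair of ubiquitin ligases of muscle atrophy, Trim63, which was higher, and Fbxo32, which was its only lower member. Myogenic regulators had 4 named genes of 32, too few for the test. Of these, the satellite cell factor Pax7 was 1.51-fold lower (log2 difference −0.60 ± 0.08; limma adjusted p = 0.178) and passed, Notch1 was lower at −0.58 ± 0.10, and Mstn (1.07 ± 0.19) and Id2 (0.95 ± 0.14), both inhibitors of muscle formation or growth, were higher. The last 3 did not pass.

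**Figure D2:**
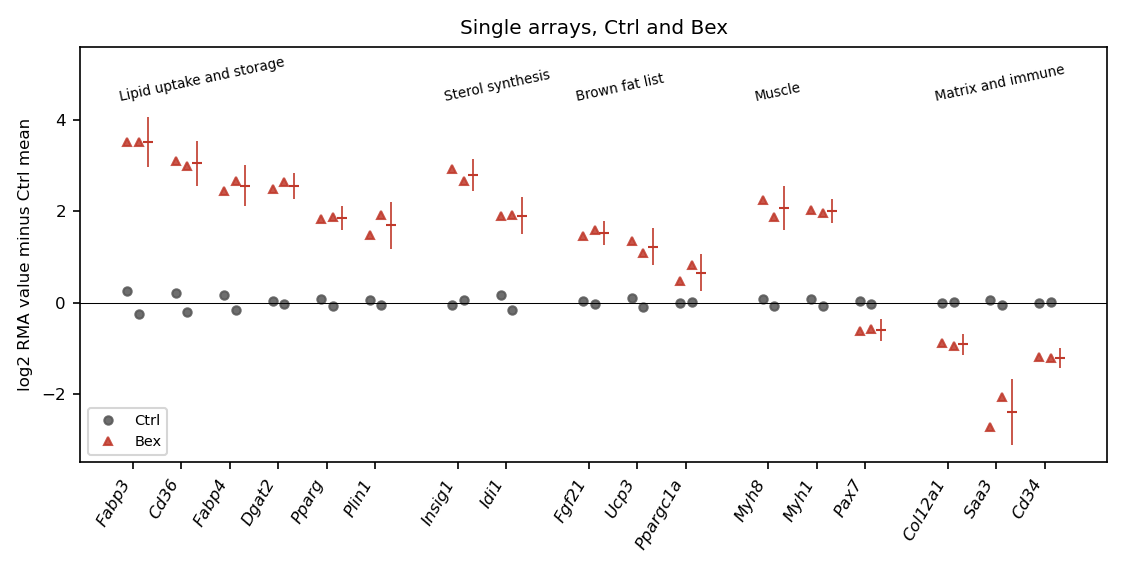
Log2 RMA value of each array minus the Ctrl mean (vertical axis) for named genes grouped by theme rather than by fixed list (horizontal axis). Grey circles are Ctrl, red triangles are Bex, and a bar gives the mean difference with its 95% confidence interval from limma. For each gene both Bex arrays lie on the same side of both Ctrl arrays, which selection for the authors' table largely forces. Fabp3 is highest at 3.51 and Saa3 lowest at −2.40.

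Extracellular matrix genes went the other way, with 1 higher and 10 lower of 42 listed (adjusted exact p = 0.00201), and 7 passed. These 7 calls rest on the variance-trend fit. The main test passed 0 matrix genes at an adjusted p of 0.1, and also 0 at 0.05 with the clusters of lowest mean left out. Col12a1 was 1.88-fold lower (log2 difference −0.91 ± 0.08), and Col4a1, Col4a2, Mmp2, Thbs1 and Dcn were also lower, whereas Col6a2 was 2.07-fold higher (1.05 ± 0.12). Inflammatory genes were 1 higher and 5 lower of 26 listed and did not pass as a list (adjusted exact p = 0.0584). Saa3 was the lowest of them and Ptgs2, the inducible cyclooxygenase, was 2.61-fold higher (1.38 ± 0.14). Both named smooth muscle genes were lower, Tagln at −1.04 ± 0.12 and Actg2 at −0.87 ± 0.09, and only Actg2 passed. Among fibroblast and progenitor genes, the surface marker Cd34 was 2.32-fold lower (log2 difference −1.21 ± 0.08), Ly6a was lower, and Fap, dim on the Ctrl arrays, was higher at 0.96 ± 0.22 without passing.

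Retinoid-responsive genes were named in 5 of 33 cases, 4 higher and 1 lower, without passing as a list (adjusted exact p = 0.715). Dhrs3, a retinaldehyde reductase, was 3.30-fold higher (1.72 ± 0.08), and Tgm2, a transglutaminase, was 2.17-fold higher (1.12 ± 0.14). Rara, a retinoic acid receptor, was 1.54-fold lower (log2 difference −0.62 ± 0.10) and did not pass. With Pparg it made up the 2 named genes of the RXR partner list.

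The 7 named genes of the unfolded protein response, of 30 listed, were all higher, including Chac1 at 2.06-fold (1.04 ± 0.09), and did not pass as a list (adjusted exact p = 0.0849). TGF-beta and BMP signalling was split into 4 higher and 3 lower (adjusted exact p = 0.716), with Bmp4 2.63-fold lower (log2 difference −1.39 ± 0.08). Too few genes were named to test the remaining lists. Glycolysis and hypoxia had 4 genes, all higher, led by the oxidoreductase gene Ero1l at 3.40-fold (1.77 ± 0.08) and by Egln3 at 1.88-fold. Heat shock had Hmox1, the haem oxygenase, at 2.80-fold (1.49 ± 0.10), and Hsph1 at 1.65-fold. The Nrf2 and metallothionein list was split into 2 higher and 2 lower, with Gstm1 1.67-fold lower. The replication gene Mcm6 (−0.97 ± 0.10) and the cyclin Ccna2 (−0.57 ± 0.08) were the 2 named cell cycle genes, and both were lower, as was Sesn1 of the arrest list (−0.88 ± 0.11). Single named genes of other lists were Pcx of the citric acid cycle list (1.25 ± 0.12), Hlf of the circadian list (0.79 ± 0.14), and Cd14 of the macrophage list (0.90 ± 0.16). Spp1 was the only named vitamin D and thyroid target (0.99 ± 0.08) and, with Dmp1 lower (−0.61 ± 0.08), made up the named bone and cartilage genes. Jag1 (0.76 ± 0.08) and Notch1 were those of Wnt and Notch signalling. Of the genes in this paragraph with no list test, Dmp1, Hlf, Cd14, Jag1 and Notch1 did not pass. No gene of the nuclear respiratory chain, interferon, endothelial, or epithelial and neural lists was named.

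**Figure D3:**
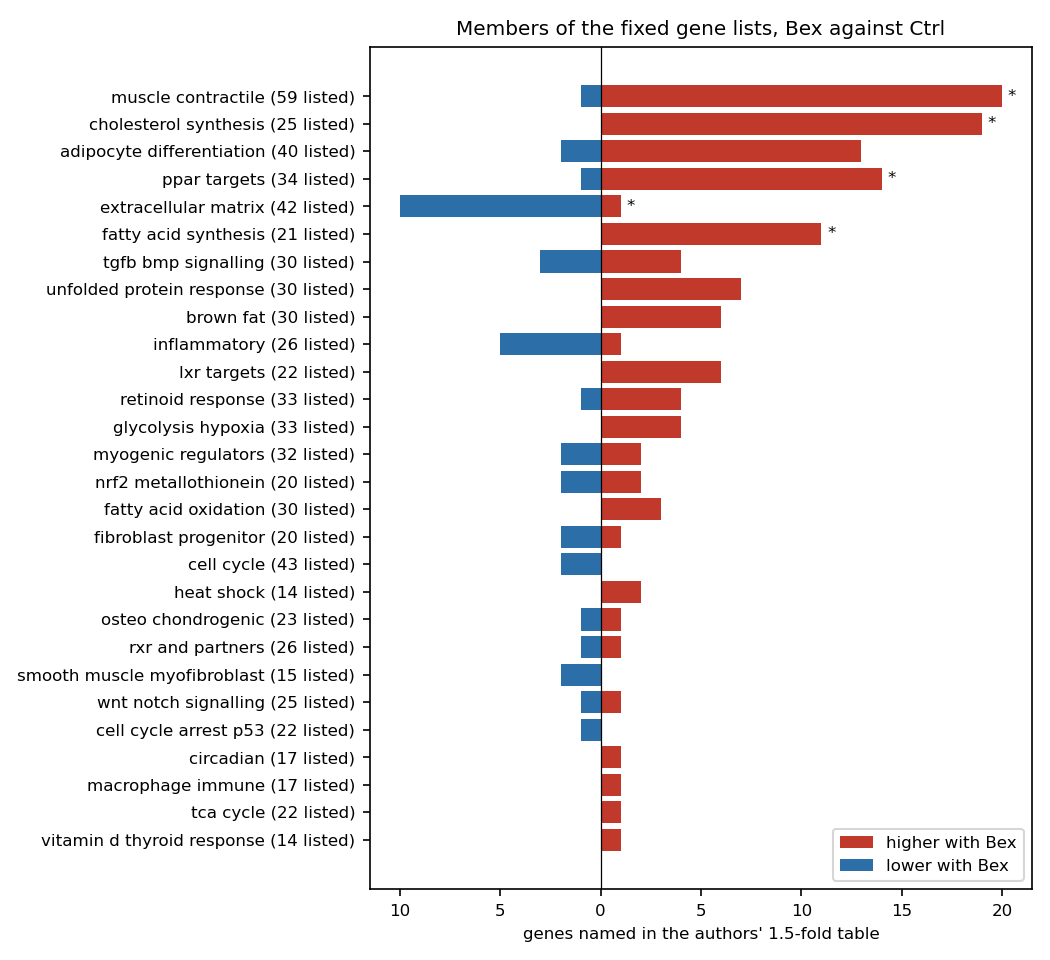
Number of genes higher (red, to the right) and lower (blue, to the left) with Bex in each fixed list with at least 1 named gene (vertical axis, with the number of genes listed), among genes of the authors' deposited table. An asterisk marks the 5 lists past an adjusted exact p of 0.05, among them cholesterol synthesis with 19 higher and 0 lower and extracellular matrix with 1 higher and 10 lower.

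The largest named differences outside these lists were chosen after the values were seen. Sprr2g, a small proline-rich protein of the epidermal barrier, was 19.8-fold higher (4.31 ± 0.19), Ear11, an eosinophil-associated ribonuclease, 10.5-fold (3.39 ± 0.15), Csn3, the milk protein kappa-casein, 9.03-fold (3.17 ± 0.17), Mgll, a monoacylglycerol lipase, 6.99-fold (2.80 ± 0.15), and Tpsab1, a mast cell tryptase, 6.18-fold (2.63 ± 0.11). On the lower side, 4930486L24Rik was 7.84-fold lower (log2 difference −2.97 ± 0.16), the alcohol dehydrogenase Adh1 5.98-fold (−2.58 ± 0.17), the acute-phase protein Orm1 5.49-fold (−2.46 ± 0.11), the growth factor Ptn 5.46-fold (−2.45 ± 0.14) and Islr 3.85-fold (−1.95 ± 0.09). All 10 passed. The Ctrl values of Sprr2g, 3.66 and 4.11, lie under the limit of 4.57 used for dim clusters and were not shown to be above background. Its fold and rank are therefore uncertain. Those of Ear11, 4.58 and 4.89, and of Cd36, 5.01 and 4.59, lie close above that limit, so the folds of both are uncertain too. Sprr2g, Ear11, Orm1 and Saa3 belong to families of near-identical copies, and Fabp3 had a second cluster at 3.65 ± 0.22 that may share its probes, so which copy changed is uncertain. Among clusters not named here, 1769 differed by 1.5-fold or more, but 1363 of these have IDs below those of the authors' table and may be array controls. Of the other 406, 10362422 (2.22 ± 0.23) and 10523547 (2.17 ± 0.19) were higher. The Ctrl values of 10362422, 4.46 and 3.87, also lie under the limit of 4.57, so its difference is uncertain.

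Set against the value table, all 559 clusters of the authors' deposited table had the same direction, 523 also differed by 1.5-fold or more and 438 did so in both same-numbered pairs. The FDR p-values in the authors' deposited table ran from 0.0998 to 0.461, with 0 under 0.05. Pearson's r between the log2 fold changes of both sources was 0.997 across these clusters, which come from the same arrays and are not independent.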

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

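The settings described as added were chosen after the data were seen. The main count of 0 clusters stayed at 0 after a median shift, after quantile normalization and with the mean of a gene's clusters. RMA had already quantile-normalized the values, so a further quantile normalization could change little. A 1.5-fold cutoff added to the test can only leave 0 at 0. The count became 427 with a variance trend, 105 with the lowest 30% of clusters left out, 80 at an adjusted p of 0.1 and 2292 with no test and 1.5-fold alone. Among added settings it became 859 with trend and filter together, 297 without the 6669 clusters whose IDs lie below those of the authors' table and which may be mostly array controls (their removal also lowers the count at 1.5-fold alone to 929, 575 higher and 354 lower), 1 with a plain ANOVA, and 0 to 32 with the trend and each array left out. With an array left out, 1 group has a single array and the spread comes from the other group alone, so these counts say little of stability. The filter and the ID limit test fewer clusters, and the trend fit and the filter shared 104 calls; the cause of the other changes was not tested. With the replicate block the count was 0, also at an adjusted p of 0.1, and with trend and replicate block it was 158; the numbers are not known to mark batches, and same-numbered arrays did not deviate together (correlation 0.0079). With no test, a median shift moved the split from 1288 higher and 1004 lower to 1399 and 904. Splitting the arrays by replicate number instead gave 1571 clusters at 1.5-fold alone, and the remaining equal split gave 1444, against 2292 for Bex against Ctrl. Much of the count at 1.5-fold alone may thus be spread between arrays. Of the 51 genes named by rule, 0 reversed under any setting; 39 passed with the trend and 23 with the filter. The count of 5 lists changed only with 1.5-fold required in each pair, an added setting that left 3, and the cause was not tested. Directions of listed genes cannot flip between pairs, because all 559 clusters share their sign in both, so this says nothing of stability. The overlap of 523 clusters with the authors' table at 1.5-fold or more was 438 to 519 under its alternatives. Camera with a preset or estimated correlation, its rank version and fry were not run. Replicate spread rises at low levels, which limits calls there.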

Other observations

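Tests on glucocorticoid genes, muscle genes, table offsets and array splits were chosen after the results were seen; the test on neighbouring genes was not. Of 30 genes known to respond to glucocorticoids, listed after the names had been seen, 16 were named, 4 higher with Bex and 12 lower. Lower were among others Fkbp5 (−1.06 ± 0.11), Tsc22d3 (−0.87 ± 0.09) and Sgk1 (−0.68 ± 0.12; not past the variance-trend fit). The split gave a Fisher's exact p of 0.00265 against 332 higher and 188 lower among other named genes, which decides nothing, as the list was not independent of the data. Higher were Trim63, Ddit4, Angptl4 and Mstn. One hypothesis is that Bex may lower the response to a glucocorticoid in the medium, whose makeup the labels do not give. Orm1, Orm3 and Saa3 also respond to inflammation, and the hypothesis stays open.

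Of the 21 named contractile genes 20 were higher with Bex than with Ctrl, both in the same medium, and the rest of the 59 listed genes were not analysed here. Signal shared between myosin heavy chain copies could account for part of it, but outside that family 16 of 17 named genes were higher (Fisher's exact p = 0.00441), which argues against it as the whole cause. With a single odd dish left out, listed contractile genes would be expected to differ no more often than other clusters, yet at least 20 of the 59 (33.9%), the same 20 genes each time, were 1.5-fold or more higher whichever array was left out, against 4.17% to 5.25% of all clusters (highest Fisher's exact p = 9.01e-12, over genes that are not independent). Unnamed genes counted as not reaching 1.5-fold there, so selection by the authors cannot raise the share. Those 20 genes had passed the authors' cutoffs on all 4 arrays, which largely forces them to hold with any array left out. The 4 counts are thus not separate tests, and only the share of 33.9% argues against a single odd dish, for these 20 genes. The labels do not tie arrays to batches of cells, so batches that coincide with the groups stay open. An effect of Bex on differentiation remains a hypothesis, untested beyond these arrays.

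Named genes lying within 5 genes of each other on a chromosome tended to change the same way. Of 104 such pairs 70.2% shared a direction, against a mean of 53.1% with shuffled directions (permutation p = 0.00040). Probes shared between neighbouring copies may explain the pairs of a single gene family, taken here as symbols that begin with the same letters. Of these pairs 15 of 16 shared a direction, including Myh1 and Myh4, Orm1 and Orm3, and Fads1 and Fads2. The rule is rough, as it also pairs Col6a2 with Col18a1 and can miss related genes with unlike symbols. Among the 88 pairs of different families by this rule the share was still 65.9%, above the 62.5% that marks the top 5% of shuffles (permutation p = 0.0111). As far as the rule separates copies, this argues against shared probes as the whole cause. Co-regulation of neighbours stays open as a hypothesis.

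The offsets between the authors' averages and the value table were shared by both groups (correlation 0.824 across 559 clusters), which is consistent with another probe summary behind the authors' table. Of the 3 ways to split the 4 arrays in equal groups, 1, the real one, gave as many as 4189 clusters at an unadjusted p below 0.05, and the highest of the others gave 1320. With 3 splits no share under 0.05 can be reached.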
